A study of Mus musculus with 12 samples.

How the data were processed

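Messenger RNA was measured by sequencing in adipose tissue of wild-type C57BL/6J mice, 3 libraries in each of 4 groups, collected at day 7: untreated adult mice, adult mice with a scald burn, untreated aged mice and aged mice with a scald burn. Per the labels' protocols, mice were immersed in a bath at 98 °C, for 10 s on the back for a burn of 20% of the body surface, and adult mice for a further 2 s on the belly for another 10%, so that adult burns covered 30% and aged burns 20% of the body surface. The depot, sex and ages in weeks are not given in the sources used here. The labels number the libraries but do not say outright that each came from its own mouse, so p-values measure the spread between these libraries.

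Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected and libraries were made with a directional kit. Per the submitters' processing notes, reads were handled with FastQC, MultiQC, cutadapt, HISAT2 and featureCounts on mm10; versions, annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands may be shared. The deposited values are raw gene counts in 1 table for adult and 1 for aged mice, with the same 27179 Entrez gene identifiers. Age therefore goes with the table, with any difference in processing between the tables and, for burned mice, with burn size. Of the identifiers, 25275 matched a gene name of assembly GRCm38.p6, and the unmatched ones held 0.366% to 0.76% of a library's counts.

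Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM scaling and quasi-likelihood F tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. Burn was tested within each age on its 6 libraries. The difference between the burn responses (aged minus adult) and the difference between aged and adult controls were tested in a model with 1 mean per group over all 12 libraries. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values were scaled by TMM over the 12 libraries and are given as mean ± SD, n = 3. Intervals given for ratios cover counting error only.

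Before the data were examined, 53 gene lists were fixed, among them lists of tissues and cells that dissected fat can hold (B cells, skeletal muscle, skin, mammary epithelium, mesothelium, male reproductive tract, exocrine pancreas and erythroid cells). Lists with at least 5 tested members were tested with camera (limma 3.58.1, correlation 0.01), beside camera with an estimated correlation and fry, adjusted over the lists of a comparison. Named genes were fixed by rule: per comparison the 8 largest increases and decreases among called genes whose groups do not overlap and whose higher group mean is at least 5 CPM in the comparison's own scaling (P4ha3 passed there and is at 4.9 CPM when scaled over the 12 libraries), leaving out unnamed gene models, pseudogenes and receptor segments; per list 2 called members with the smallest adjusted p or else the 2 most abundant; and 10 genes named regardless of outcome. Other called members of a list are named to fill out its count. A result selected by these rules is not reported here.

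Alternatives were other scalings and count filters, DESeq2 1.42.0, limma-voom with and without quality weights, a fold threshold, the replicate number as a block, other sets of libraries in the fit and each library left out in turn. A further alternative, leaving out Adult control 1 and Adult burn 1 together, was chosen after seeing the data. The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For burn in adult mice, over 14600 genes, 6 of the 2-fold and 55 of the 4-fold changes were recovered; for burn in aged mice, over 15132 genes, 12 and 66. For the difference between ages, over 15553 genes, 2 and 37 were recovered, and for aged against adult controls, over 15553 genes, 16 and 74. Of the calls made, 10.1%, 5.88%, 7.14% and 4.12% were unchanged genes, in the same order, so all but the last exceeded the threshold of 0.05. No 2 libraries of a group agreed within sampling noise: the chi-square of their counts per degree of freedom was at least 29.5.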

Results

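Adipose tissue was profiled in 12 libraries, 3 from each of 4 groups, to ask whether a burn gives different transcript profiles in adult and aged mice. Total counts were 25231506 to 32236330 in adult and 31846557 to 46531070 in aged libraries. Within groups, Spearman correlations between libraries were 0.912 to 0.977 in adult controls, 0.976 to 0.986 after burn in adults, 0.989 to 0.994 in aged controls and 0.922 to 0.982 after burn in aged mice. The first principal component held 44.4% of the variance, and Aged burn 2 lay furthest out on it.

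Some libraries stood apart within their group. Adult control 1 carried lymphocyte transcripts: the B cell receptor subunit gene Cd79a was at 270 CPM there and at most 0.935 CPM in each other adult library, and the T cell gene Cd3e at 69.4 CPM against at most 1.24. Adult burn 1 carried skeletal muscle transcripts, with Acta1 (skeletal actin) at 735 CPM against 16.6 and 6.47 in the other burned adults. In Aged burn 2 the mean log2(CPM + 1) of 13 neutrophil genes was 5.85, against 1.94 and 1.75 in the other burned aged mice. Adult burn 3 stood above the other burned adults for cell cycle genes (3.03 against 1.86 and 1.82). The same held for genes of lipid-associated macrophages (6.87 against 5.18 and 5.28), but not for macrophage genes (5.77 against 5.13 and 6.02).

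**Figure D1:**
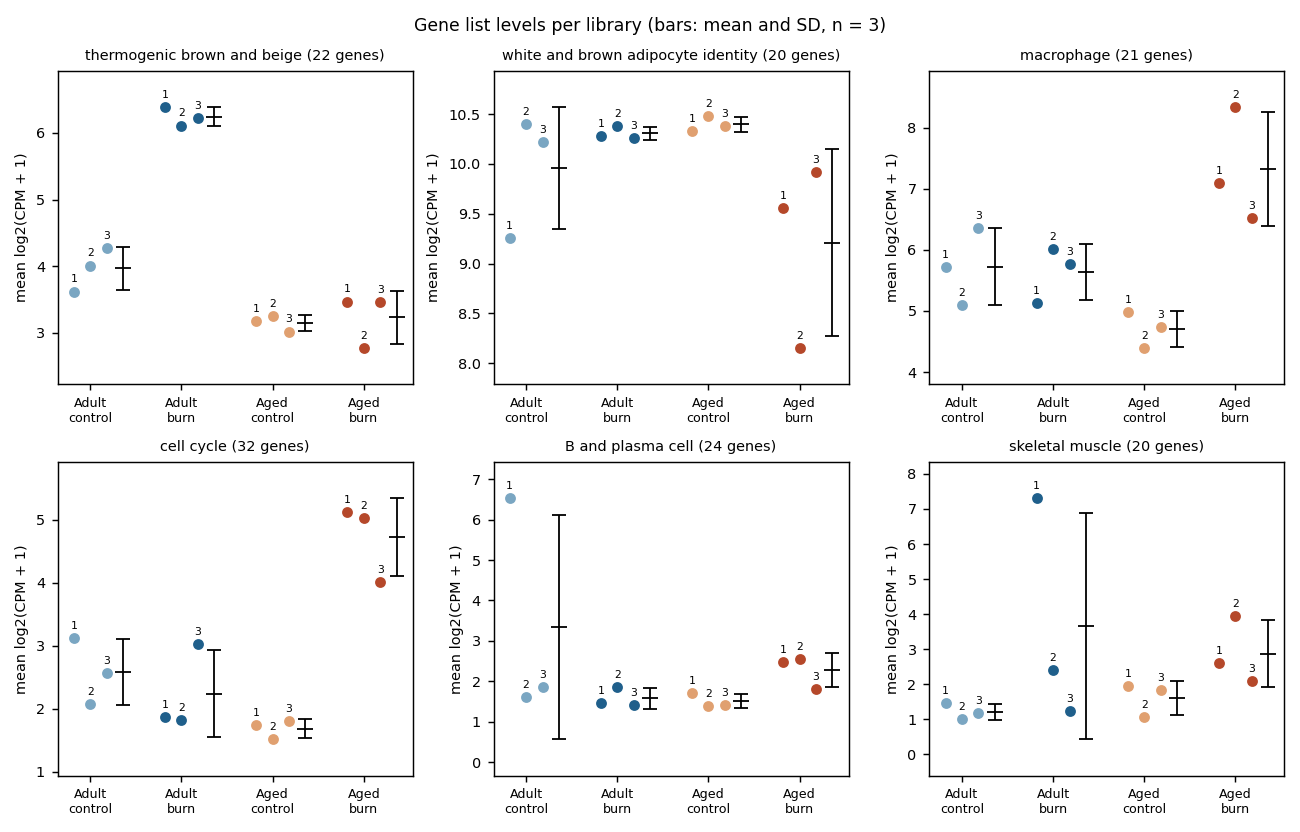
Mean log2(CPM + 1) of 6 gene lists in each library; numbered points are libraries and bars the mean and SD of 3. Thermogenic genes stand at 6.11 to 6.39 in burned adults and at most 4.27 in every other library, while B cell genes stand at 6.53 in Adult control 1 alone.

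The first comparison asked what burn did to adult fat. Ucp1, Fabp3, Dio2 and Gk, 4 of 21 tested genes of heat-producing brown and beige adipocytes, rose in burned adult mice. Ucp1, the uncoupling protein of brown fat mitochondria, went from 15.7 ± 6.22 to 1080 ± 92.9 CPM (SD, n = 3; log2 fold change 6.10 ± 0.37 SE, edgeR adjusted p = 0.016). Of 14600 genes, 6 passed the test, 6 up and 0 down. Beside Ucp1 these were Fabp3, a fatty acid binding protein (1.58 to 81.8 CPM, log2 5.69), Dio2, which activates thyroid hormone (2.44 to 31.2 CPM, log2 3.66), Gk, glycerol kinase (12.2 to 69.2 CPM, log2 2.49), the kininogen gene Kng2 (log2 5.38) and the receptor gene Lgr6 (log2 5.46). Ucp1 (Entrez 22227) lies on chromosome 8 from 83290348 to 83298456, Fabp3 (14077) on chromosome 4 from 130308738 to 130315463 and Dio2 (13371) on chromosome 12 from 90724552 to 90739038 of GRCm38.

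Of 21 thermogenic genes tested, 4 rose (Ucp1, Fabp3, Dio2 and Gk) and 17 did not pass over all genes. Adjusted over the list alone 18 rose, and all 21 had positive fold changes (median log2 2.25). The list passed camera (adjusted p = 2.19e-72) and fry (adjusted p = 0.00994), with adjusted p = 0.0571 with an estimated correlation. Cpt1b (log2 3.48), Cox7a1 (3.35) and Cidea (2.25) had adjusted p of 0.0528, 0.0812 and 0.651. Among the 22 fatty acid oxidation genes none was called over all genes and 10 were up adjusted over the list alone (median log2 0.79); of 19 tricarboxylic acid cycle genes 8 were (median 0.85). Of 57 nuclear genes of oxidative phosphorylation 0 were, with all 57 positive (median 0.59). Camera called these 3 lists, with adjusted p = 0.43, 0.43 and 0.748 with an estimated correlation, and fry gave adjusted p = 0.376, 0.376 and 0.763. The 13 mitochondrially encoded mRNAs were likewise all positive (median 0.93; adjusted p = 0.481 with an estimated correlation). Adult control 1 stood below the other controls on all 4 lists, with a mean log2(CPM + 1) of 7.03 against 7.83 and 8.34 for oxidative phosphorylation. Without it the medians were 0.53 (fatty acid oxidation), 0.55 (tricarboxylic acid cycle), 0.30 (oxidative phosphorylation) and 0.63 (mitochondrially encoded). Acadm, a medium-chain acyl-CoA dehydrogenase, was at 541 ± 179 CPM in controls and 1050 ± 83.4 after burn (adjusted p = 0.788).

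Lists of immune cells were lower on camera, beside the lymphocyte transcripts of Adult control 1: B and plasma cell genes had a median log2 of -4.47 and T and NK cell genes -3.17, with 0 members called in each and adjusted p = 0.748 with an estimated correlation. Without that library the medians were -0.18 and 0.06 and camera called neither. The skeletal muscle list had a median of 5.59 with 0 of 16 members called over all genes and 11 up adjusted over the list alone (adjusted p = 0.748 with an estimated correlation). Without Adult burn 1 the median was 0.99. Macrophage genes (median -0.03), matrix genes (-0.17), adipocyte identity genes (0.24), mesothelial genes (0.10) and erythroid genes (0.08) had 0 called members. Col1a1 (936 to 697 CPM), Adgre1 (62.8 to 67.2), Lep (375 to 297) and Saa3 (20.5 to 27.4) were not called. Camera called 18 lists, 13 up and 5 down, but other divisions of the same 6 libraries gave up to 29. The 6 calls depended on single libraries: 1 gene was called without Adult control 1, 0 without Adult control 2 and 0 without any 1 of the burn libraries (1660, 231, 348 and 364 genes at unadjusted p under 0.05 in edgeR). Without Adult control 3, 5 were called, 3 of them among the 6 calls. DESeq2 called 62 on all 6, and the log2 fold change of Ucp1 stayed between 5.91 and 6.48.

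**Figure D2:**
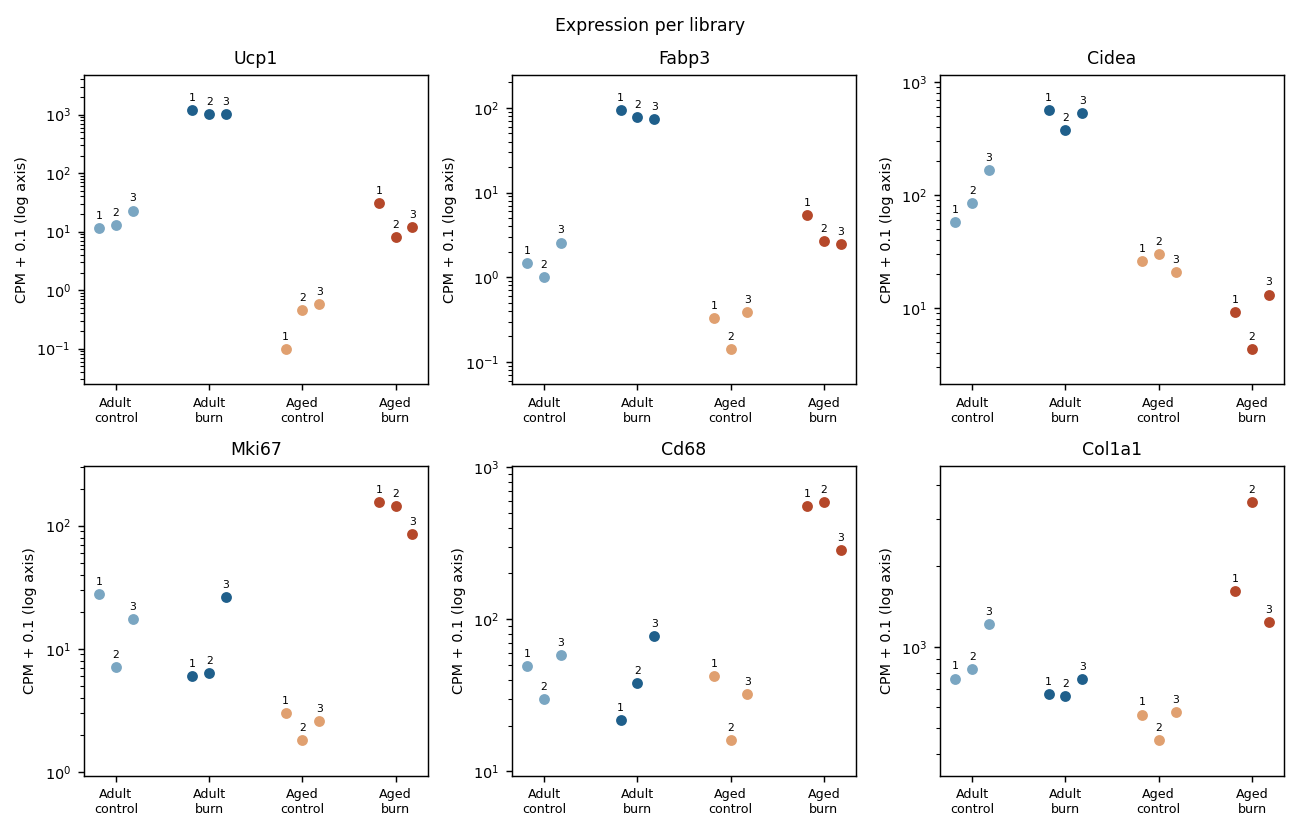
CPM + 0.1 on a log axis of 6 genes in each library, points numbered by library. Ucp1 reached 1010 to 1190 CPM in burned adults and 7.94 to 30.5 CPM in burned aged mice, and Mki67 reached 85.8 to 157 CPM in burned aged mice.

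The next comparison asked the same of aged fat, where the burn was smaller. Proliferation, macrophage and inflammatory genes rose in burned aged mice. Mki67, a marker of dividing cells, went from 2.38 ± 0.602 to 129 ± 37.8 CPM (log2 5.76 ± 0.34 SE, adjusted p = 0.00516). The macrophage gene Cd68 rose from 30.2 ± 13.3 to 478 ± 168 CPM (log2 3.99) and Adgre1, which encodes F4/80, from 24.2 ± 8 to 560 ± 402 CPM (log2 4.54). The collagen gene Col1a1 rose from 528 ± 66.8 to 2110 ± 1200 CPM (log2 2.00, adjusted p = 0.0298). In all, 2534 of 15132 genes passed edgeR's test, 2075 up and 459 down.

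Of 32 cell cycle genes 31 rose (median log2 4.13), among them Top2a (5.50), Cenpf (5.31) and Bub1 (6.26); fry gave adjusted p = 0.0282, and camera's call had adjusted p = 0.536 with an estimated correlation. Of 21 macrophage genes 17 rose (median 2.85), and of 18 genes of lipid-associated macrophages, which take up lipid in fat, 15 rose and 1, Acp5, fell. Aged burn 2 stood highest for macrophage genes, with a mean log2(CPM + 1) of 8.34 against 7.1 and 6.52 in the other burned aged mice. Nceh1 and Lipa, enzymes of cholesterol ester breakdown, rose from 7.48 to 156 and from 77.3 to 529 CPM, and Trem2 rose by log2 4.66. Adjusted over the list alone, 21 macrophage and 17 lipid-associated genes rose. Both lists had adjusted p = 0.536 by camera with an estimated correlation, and fry gave adjusted p = 0.0867 and 0.0356. Inflammatory genes rose in 16 of 25 members over all genes and 23 adjusted over the list alone, including Ccl2, which attracts monocytes (4.07 ± 2.4 to 136 ± 115 CPM), and Il1rn, the interleukin 1 receptor antagonist (1.09 ± 0.792 to 127 ± 78.5 CPM). Interferon genes rose in 11 of 28 members over all genes and 22 adjusted over the list alone, including Oasl1 and Oas2. The inflammatory and interferon lists both had adjusted p = 0.536 with an estimated correlation and fry adjusted p = 0.109. Aged burn 2 stood apart on both, with a mean log2(CPM + 1) of 6.07 against 3.68 and 3.31 for inflammatory and 5.78 against 4.76 and 4.42 for interferon genes. Neutrophil genes rose in 3 of 12 members (adjusted p = 0.586 with an estimated correlation, fry adjusted p = 0.195), beside their high level in Aged burn 2. B and plasma cell genes rose in 7 of 24 members, Cd22 and Sdc1 first (adjusted p = 0.536 with an estimated correlation, fry adjusted p = 0.0867), while Cd79a stayed at or under 3.48 CPM.

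Matrix genes rose in 11 of 34 members over all genes and 15 adjusted over the list alone (median 0.73), including the matricellular protein gene Postn (61.2 to 473 CPM) and Tgfb1 (35.6 to 161 CPM). The matrix list had adjusted p = 0.536 by camera with an estimated correlation and 0.0867 by fry. Among 18 circadian clock genes 10 fell and 2 rose: Dbp (-2.22), Ciart (-2.54) and Per2 (-1.62) fell, and Arntl (1.56) and Nfil3 (2.67) rose (fry adjusted p = 0.0356; adjusted p = 0.536 with an estimated correlation). The mean log2(CPM + 1) of clock genes was 5.32 in aged controls, 4.4 in burned aged mice, 4.48 in adult controls and 4.59 in burned adults. Aged controls were thus the group that stood apart, and the hour of collection is not among the sample details used here. The largest falls were those of Cish, an inhibitor of cytokine signalling (57.9 to 4.65 CPM, log2 -3.64), Cyp2e1 (1350 to 154 CPM), the complement gene C7 (56.1 to 8.45 CPM), Ciart, Inmt, Rassf6, Sult1e1 and Mpzl2. In adult controls Cish was at 6.4 CPM. The largest increases, in Cxcl5, Arg1, Crabp1, Nptx1, Clec4e, Mmp8, P4ha3 and Slfn4, started near 0: P4ha3 had 1 read in the 3 controls, a ratio of 510 (95% counting interval 91.6 to 20200), and was at 2.75, 10.3 and 1.65 CPM in the burned aged libraries. Cxcl5 also had 1 read in the controls, and its level after burn lay mainly in Aged burn 2 (417 CPM, against 1.39 and 3.85 in the others), so that its pooled ratio of 19300 (3470 to 764000) rests on that library. Arginase Arg1 went from 0.041 ± 0.018 to 483 ± 597 CPM. In burned aged mice Crabp1 (37.9 ± 60.9 CPM), Clec4e (31.9 ± 48.6), Mmp8 (8.97 ± 14.5) and Slfn4 (58 ± 94.5) also had SDs above their means. The sizes of these increases therefore rest largely on single libraries.

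Adipocyte identity genes were lower as a list on camera (median log2 -1.04, all 20 negative, camera adjusted p = 1.01e-05). With an estimated correlation adjusted p was 0.536, and fry gave adjusted p = 0.11. Of the members only Retn passed, which fell from 1100 to 375 CPM, while Adipoq was at 4080 ± 158 and 2060 ± 1170 CPM (adjusted p = 0.212). Lipolysis genes had a median of -1.10 with 0 of 18 called (adjusted p = 0.536 with an estimated correlation, fry adjusted p = 0.109). Aged burn 2 stood lowest on both lists (8.15 against 9.56 and 9.92 for adipocyte identity, 5.88 against 7.05 and 7.45 for lipolysis), and without it the median of adipocyte identity genes was -0.70. Of 21 thermogenic genes 5 rose and 3 fell, with 7 up and 3 down adjusted over the list alone, and camera did not call the list (median -0.25, mean 0.35; camera adjusted p = 0.928). Ucp1 rose from 0.276 ± 0.248 to 16.8 ± 12.1 CPM (log2 5.85 ± 0.99 SE, adjusted p = 0.0141). Fabp3, Dio2, Acot11 and Cox7a1 also rose, and Cidea, Ppargc1a and Otop1 fell. Of 18 lipogenesis genes 2 fell, Aacs (160 to 56.1 CPM) and Slc25a1, and of 13 mitochondrially encoded mRNAs 3 fell (mt-Nd3, mt-Co2 and mt-Co3). In aged controls mt-Nd3 and mt-Co2 were at 16.1 and 16.6 CPM, far below mt-Co1 at 18900 CPM. Why so few reads were counted for them was not tested. Of 57 oxidative phosphorylation genes 3 fell, among them Ndufa5 (-0.57). Aged burn 2 also stood lowest for lipogenesis (mean log2(CPM + 1) 6.09 against 6.82 and 7.06) and mitochondrially encoded genes (6.91 against 7.48 and 7.47). The lipogenesis, mitochondrially encoded and oxidative phosphorylation lists passed camera, with adjusted p = 0.536 with an estimated correlation. Fry gave them adjusted p = 0.109, 0.0785 and 0.0867. The skeletal muscle list was higher on camera (median 2.16; 2 of 19 up and 1 down; adjusted p = 0.594 with an estimated correlation), beside Acta1 at 115 CPM in Aged burn 2 against 32.3 and 11.1 in the other burned aged mice. Without Aged burn 2 camera did not call the skeletal muscle list (median 1.36, adjusted p = 0.107). Saa3 (1.06 to 1440 ± 2460 CPM), Il6, Lep, Fkbp5 and Cdkn2a were not called, with adjusted p of 0.0504, 0.0731, 0.147, 0.41 and 0.0693. Mesothelial (median -0.31) and erythroid (0.01) lists had 0 called members. Camera called 28 lists, and other divisions of the 6 libraries gave up to 34. The count of genes was 0 without Aged control 3 (4227 at unadjusted p under 0.05 in edgeR), 575 without Aged control 1 and 410 without Aged control 2. It was 872 without Aged burn 1, 3265 without Aged burn 2 and 5743 without Aged burn 3, while DESeq2 called 5011 on all 6.

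The difference between the burn responses was tested next. The log2 response to burn was larger in aged than in adult mice for 29 of 32 cell cycle genes and 15 of 21 macrophage genes and smaller for 11 of 22 thermogenic genes. It was larger by 6.21 for Mki67, 3.98 for Cd68 and 2.43 for Col1a1 (adjusted p = 0.0169, 0.0169 and 0.0211). Cidea, a lipid droplet protein of brown fat, went from 103 to 491 CPM in adults and from 25.5 to 8.77 CPM in aged mice (log2 difference -3.80 ± 0.62 SE, adjusted p = 0.0169). Of 15553 genes, 1845 passed, 1500 with a larger and 345 with a smaller log2 response in aged mice. Age cannot be told apart here from burn size or from the table.

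Of 22 thermogenic genes 11 had a smaller response in aged mice over all genes and 15 adjusted over the list alone (median difference -1.77; fry adjusted p = 0.0102; adjusted p = 0.394 with an estimated correlation), among them Slc27a2 (-5.70), Ppargc1a (-2.81) and Dio2 (-2.01). Ucp1 was not among them: its difference was -0.27 (edgeR adjusted p = 0.867). Its level in aged controls was near 0 (0.276 ± 0.248 CPM), so equal log2 responses do not mean equal levels. Burned aged mice reached 16.8 ± 12.1 CPM, against 15.7 ± 6.22 CPM in adult controls and 1080 ± 92.9 CPM in burned adults. Fatty acid oxidation genes were lower in 14 of 22 members over all genes and 21 adjusted over the list alone, such as Acaa2 (-1.82), with Cpt1a (1.13) opposite. Tricarboxylic acid cycle genes were lower in 7 of 19 members and 18 adjusted over the list alone, such as Suclg1 (-1.81). Fry gave adjusted p = 0.0305 and 0.0283, and both had adjusted p = 0.398 with an estimated correlation. Their median differences (-1.51 and -1.37) were close to that of adipocyte identity genes (-1.34). Whether a different share of adipocytes lies behind them was not tested. Cell cycle genes were higher in 29 of 32 members, macrophage genes in 15 of 21 and matrix genes in 8 of 34 (31, 20 and 16 adjusted over the list alone; fry adjusted p = 0.0187, 0.0305 and 0.0305; adjusted p = 0.398 with an estimated correlation for each). B and plasma cell genes were higher in 8 of 24 members (median 7.43; adjusted p = 0.406 with an estimated correlation), beside the level of Cd79a in Adult control 1. The same library enlarged the differences of H2-Eb2, Apol7c and Cd22, which were at 47.3, 59.5 and 263 CPM there. Without Adult control 1 the difference of Cd22 was 4.28 and still called, and H2-Eb2 (4.55) and Apol7c (3.89) were not called.

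Calls of the difference depended on single libraries: 0 genes were called without Adult burn 1, without Adult burn 2, without Aged control 2 or without Aged control 3 (4273, 4561, 4353 and 4489 at unadjusted p under 0.05 in edgeR). The count was 354 without Aged control 1, 719 without Aged burn 1, 811 without Aged burn 2, 915 without Adult burn 3 and 1245 without Adult control 1. It was 2503 without Adult control 3, 2897 without Adult control 2, 4039 without Aged burn 3 and 3783 by DESeq2 on all 12. Without Adult control 1 and Adult burn 1 together, a setting chosen after seeing the data, 0 were called (3450 at unadjusted p under 0.05).

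Across 14421 genes tested in both ages, the log2 fold changes had a Spearman correlation of -0.359 (Pearson -0.255); this is across genes, which are not independent replicates. Other divisions of the libraries gave correlations up to 0.623 from 0 in size, the value was -0.073 without Adult control 1, and it was 0.08 without Adult control 1 and Adult burn 1. Up in both ages were 3 genes (Ucp1, Fabp3 and Dio2) where 0.665 would be shared by independent lists; 0 were called in opposite directions.

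**Figure D3:**
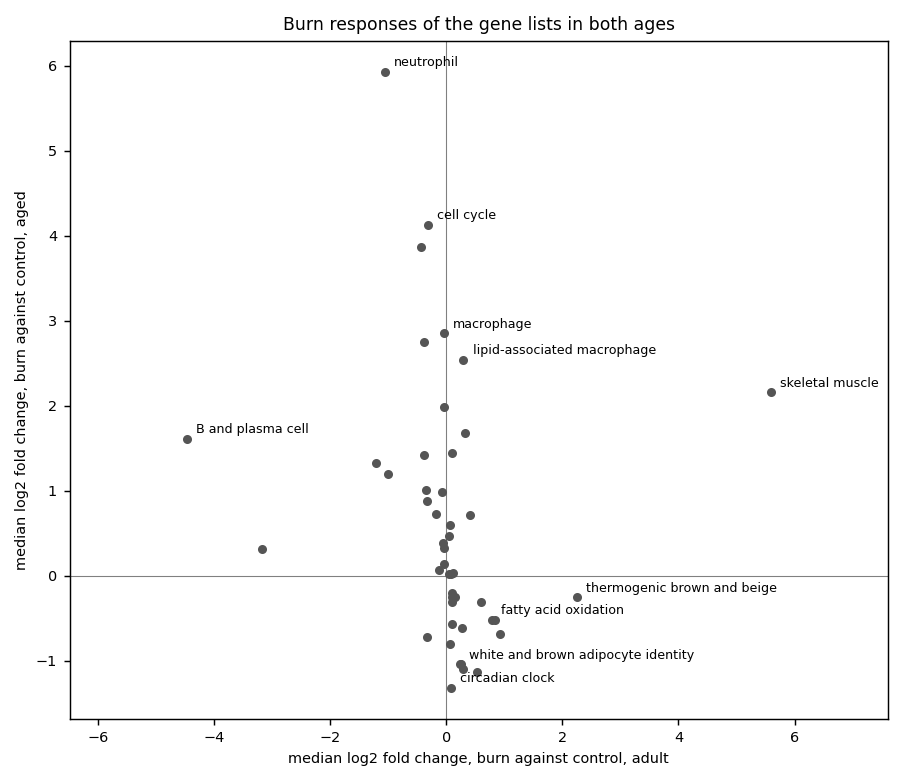
Median log2 fold change of each gene list with at least 5 tested members, burn against control, in adult (x axis) and aged mice (y axis). Cell cycle genes stand at -0.31 (-1.27 to 0.07 with single libraries left out) and 4.13 and thermogenic genes at 2.25 and -0.25; the B cell and muscle lists are set on the x axis by Adult control 1 and Adult burn 1.

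Aged and adult control mice were compared last. Acly, Elovl6 and Scd2, of fatty acid synthesis, and Ucp1 were lower in aged than in adult controls, and the clock gene Bhlhe41 was higher. Acly, which makes acetyl-CoA for fatty acid synthesis, was at 1590 ± 1050 CPM in adult and 165 ± 29.8 CPM in aged controls (log2 -3.27 ± 0.48 SE, adjusted p = 0.031). Ucp1 was at 15.7 and 0.276 CPM (log2 -5.74, adjusted p = 0.0245), and Bhlhe41 at 6.24 ± 2.13 and 39.3 ± 7.17 CPM (log2 2.65, adjusted p = 0.0238). In all, 66 of 15553 genes passed, 37 higher and 29 lower in aged controls.

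Higher in aged controls were also Chrna5, Kcnj15, Vgll3, Bcat1, Trim16 and Spsb1, and lower were the fructose transporter Slc2a5 (10.6 to 0.143 CPM), Sorcs2, Itm2a (35.2 to 2.94 CPM), Elovl6 (243 to 22.2 CPM), Rgs2 and Itih4. Of 18 lipogenesis genes 3 were lower (Acly, Scd2 and Elovl6) and 12 adjusted over the list alone (median -1.44; fry adjusted p = 0.137; adjusted p = 0.697 with an estimated correlation). Of 22 thermogenic genes 2 were lower, Ucp1 and Dio2, and 10 adjusted over the list alone (median -1.10; adjusted p = 0.697 with an estimated correlation). Clock genes were higher as a list (median 1.11; 1 of 18 called, and 10 up and 3 down adjusted over the list alone; adjusted p = 0.502 with an estimated correlation). The same aged control libraries entered the fall of clock genes after burn, so these clock results are not independent. T and NK cell genes (median -4.43) and B and plasma cell genes (-6.29) were lower on camera with 0 members called (adjusted p = 0.718 and 0.741 with an estimated correlation), beside the lymphocyte transcripts of Adult control 1. Cell cycle genes (median -1.55) and macrophage genes (-1.22) were also lower on camera (adjusted p = 1.72e-09 and 6.37e-05), with 0 members called and adjusted p = 0.741 each with an estimated correlation. These lower medians and the larger burn responses in aged mice are not independent results, since both comparisons use the same control libraries. For cell cycle genes Adult control 1 stood highest of the adult controls (mean log2(CPM + 1) 3.12 against 2.07 and 2.57). Lep was at 375 ± 231 and 2210 ± 1170 CPM (adjusted p = 0.0805). Fry called 0 lists and camera 18, and other divisions of the 6 control libraries gave up to 27.

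The 66 calls depended on single libraries and on the burned groups sharing the fit: 0 genes were called from the 6 control libraries alone (3599 at unadjusted p under 0.05 in edgeR) and 2184 by DESeq2. The count was 0 without Adult control 3, without Aged control 1 or without Aged control 3 (3634, 3149 and 2550 at unadjusted p under 0.05), 3 to 38 without Aged control 2, Adult burn 1, Adult burn 2, Aged burn 1, Adult burn 3 or Adult control 1, 789 without Aged burn 2 and 2011 without Adult control 2. Lists of skin, mammary epithelium, visceral depot genes, male reproductive tract and exocrine pancreas had fewer than 5 tested members in every comparison and 0 called members; Krt10 was at 2.18 to 4.66 CPM and Cela1 at 13.6 to 47.2 CPM in the group means.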

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

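Tests of the erythroid level, adipocyte share, Cd79a to Mki67 ratio, thermogenic medians without a library, and all counts over other divisions of the libraries were chosen only after the results were seen.

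The burn response differed between ages by the interaction test for 1845 genes. The largest log2 differences (aged minus adult) were 13.57 for Cemip, 11.15 for Cxcr2, 10.64 for H2-Eb2, 10.21 for Il1b, 10.09 for Apol7c, 10.09 for Cd22, 10.05 for Slc7a11 and 9.97 for Clec4e, and -5.70 for Slc27a2, -4.72 for Cish, -3.92 for Kng2, -3.80 for Cidea, -3.78 for Ntrk3, -3.60 for Tbx1, -3.58 for Mpzl2 and -3.47 for Me3. Cemip had 0 ± 0 CPM in aged controls, so its fitted value depends on the prior count and is no bound. Cish was at 57.9 ± 30 CPM in aged controls against 6.4 ± 5.02 CPM in adult controls. In burned aged mice Cxcr2 (59.4 CPM against 1.06 and 0.754), Il1b (363 against 2.17 and 1.43), Clec4e (88 against 6.34 and 1.45) and Slc7a11 (20.8 against 2.04 and 1.28) lay mainly in Aged burn 2. Slc7a11 was also at 12.6 CPM in Adult control 1 and at most 0.0645 in the other adult controls, so these differences rest largely on single libraries. Of the gene lists, 17 were called higher and 13 lower by camera, and none of these calls held with an estimated correlation. The higher ones had median log2 differences of 4.06 for inflammatory cytokine and NF-kB response, 1.28 for type I interferon response, 2.98 for MHC class II antigen presentation, 3.06 for macrophage, 2.50 for lipid-associated macrophage, 3.24 for monocyte, 8.84 for neutrophil, 1.31 for mast cell eosinophil and type 2 response, 3.83 for T and NK cell, 7.43 for B and plasma cell, 2.06 for dendritic cell, 0.97 for extracellular matrix and fibrosis, 1.26 for matrix metalloproteinase and inhibitor, 2.02 for lymphatic endothelial, 4.64 for cell cycle, 2.22 for senescence and secretory phenotype, 1.22 for immediate early. The lower ones had medians of -1.34 for white and brown adipocyte identity, -1.77 for thermogenic brown and beige, -1.64 for de novo lipogenesis, -1.36 for lipolysis, -1.34 for triglyceride synthesis and lipid droplet, -1.51 for fatty acid oxidation, -0.86 for oxidative phosphorylation nuclear encoded, -1.74 for mitochondrially encoded mRNA, -1.37 for tricarboxylic acid cycle, -0.84 for insulin signaling, -1.12 for smooth muscle and pericyte, -1.27 for circadian clock, -4.24 for skeletal muscle. Without Adult control 1 the difference was 0.16 for T and NK cell genes, no longer called, 1.82 for B and plasma cell genes, 1.40 for MHC class II and 1.52 for dendritic cell genes. Without Aged burn 2 it was 3.53 for neutrophil, 2.00 for monocyte and 2.34 for macrophage genes, and without Adult burn 1 that of skeletal muscle was 0.36, no longer called.

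B and T cell transcripts stood in Adult control 1. Of 5 lymph node stroma genes named before their values were seen, 4 (Glycam1, Ccl19, Madcam1 and Chst4) were at over 4 times the highest other adult library; Glycam1, made by lymph node vessels, was at 58.7 CPM there and at most 0.116 CPM in the others, and Cxcl13 at 86.4 CPM was below the 93 CPM of Adult burn 2. Blood is argued against: the mean log2(CPM + 1) of erythroid genes was 2.78 in this library and 5.11 and 5.25 in the other adult controls. A lymph node dissected with the fat is a candidate explanation; the design names no group that sets this library apart, so no biological explanation was tested.

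Macrophage and cell cycle genes were higher after burn in aged mice. A lower share of adipocytes alone would raise the markers of all other cells, but the median log2 fold change of macrophage genes exceeded those of endothelial, smooth muscle and Schwann genes (0.03, -0.62 and -0.72) by at least 2.82. Lymph node tissue would bring B cell genes: the ratio of Cd79a to Mki67 was at most 0.0223 in burned aged mice and 9.75 in Adult control 1; this ratio replaced a comparison of the medians of cell cycle (4.13), macrophage (2.85) and B cell genes (1.61), which did not decide. More macrophages and more dividing cells may lie behind the pattern, which was not tested. Age and the table were the same in the groups compared here. With burn size, they stay open only for the difference from adult mice.

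Thermogenic genes were higher after burn in adult mice. Without the muscle library Adult burn 1 their median log2 fold change was 2.14, and without the lymphoid library Adult control 1 it was 1.95, which argues against either library as the source. Brown fat taken with the depot cannot be told apart from a change in the white fat: the summed CPM of Zic1 and Lhx8 was 1.12 times the control mean (2.91 ± 0.711 and 3.27 ± 0.962 CPM), a value that met the bound set beforehand against brown fat, but the bound was wrong, since Zic1 lay at or under 0.12 CPM in burned adults and Lhx8 was highest in aged controls (5.09 to 8.05 CPM), where Ucp1 was at or under 0.48 CPM. Thermogenic activation of the depot may explain the pattern and stays a hypothesis.

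With 10 divisions of 6 libraries, no share under 0.05 can be reached. All numbers of divisions include the real one. The real count and the highest other were 6 and 1 genes for burn in adults, 2534 and 0 for burn in aged mice, and 66 and 0 for aged against adult controls, with 1 division of 10 as large in each case. For called lists they were 18 and 29 in adults (9 divisions as large), 28 and 34 in aged mice (4) and 18 and 27 for controls (8). For the difference between ages, 2 of 100 drawn divisions gave as many genes (1845 real, 3260 highest other). These divisions regrouped the libraries of both ages, so their share does not test whether the 2 burn responses are equal. With the aged libraries kept in their real groups, 3 of 10 divisions of the adult libraries gave as many. The others ranged from 461 to 3260, which points to the aged response as the structure behind the count. Chance is thus not excluded for a difference between ages. For lists 13 of 100 gave as many (30 real, 35 highest other), and for the correlation between ages 28 of 100 pairs of divisions lay as far from 0 (highest 0.623), so chance is not excluded for either.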

How the results depend on the processing

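Each library left out in turn was planned before the data were examined; leaving out Adult control 1 and Adult burn 1 together was chosen after seeing the data. Other scalings, count filters and the fold threshold kept each count of genes within 1.5 times. DESeq2 called 62, 5011, 3783 and 2184 genes (burn in adults, burn in aged, difference between ages, aged against adult controls), which include 6, 2523, 1808 and 66 of the reported calls. Voom with quality weights called 8390, 4064 and 334 in the last 3 and limma-voom 833 for the difference between ages; DESeq2 and the weights lowered the share of increases in burned aged mice from 81.9% to 62.1% and 52.9%, and the share of larger responses in the difference between ages from 81.3% to 61.2% and 59.6%. For age in controls the balance turned in some settings, among them from 56.1% higher to 45.3% with DESeq2, 37.8% without Adult control 2 and 44.7% without Adult control 1. The 12-library model called 14 for burn in adults, and the 6 control libraries alone 0 for age. Without Adult control 1 and Adult burn 1, 0 genes were called for burn in adults and 0 for the difference, and the correlation turned to 0.08. Leaving out single libraries gave 0 to 5 genes for burn in adults, 0 to 5743 in aged mice, 0 to 4039 for the difference, 0 to 2011 for age in controls and correlations from -0.49 to -0.073. The cause was not tested, beyond fewer samples in each fit.

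Deviations of same-numbered control and burn libraries had correlations of 0.02, 0 and 0.23 in adults and -0.12, -0.21 and -0.07 in aged mice. Those of other pairs were -0.2 to 0.17 in adults and -0.28 to 0.27 in aged mice. This gave no clear sign that the numbers pair the samples. Pairing is not excluded, since single libraries that stood apart weigh on these correlations. With the replicate block 0, 917, 0 and 8 genes were called (455 and 4480 at unadjusted p under 0.05 where edgeR called 0).

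With an estimated correlation camera called 0, 0, 0 and 0 lists, and fry 1, 9, 13 and 0. Leaving out single libraries gave 17 to 28 lists for burn in adults, 27 to 29 in aged mice, 27 to 31 for the difference and 16 to 21 for age. For burn in adults only 9 of the 17 lists called without Adult control 1 were among the 18 main calls in the same direction. Without Adult control 1 and Adult burn 1 together, 8 of 15 were. The direction of the test turned for some lists. For burn in adults, medians ranged over the libraries left out from -0.05 (without Adult control 1) to 0.48 for adipocyte identity, -0.16 (without Adult control 1) to 0.45 for acute phase, -0.03 (without Adult control 1) to 0.49 for oxidative stress, -0.22 to 0.23 (without Adult control 1) for immediate early and -0.44 (without Adult control 1) to 0.41 for erythroid genes. For cell cycle genes they ranged from -1.27 (without Adult burn 3) to 0.07 (without Adult control 1), and the call was lost without Adult control 1, Adult burn 1 or Adult burn 2. They ranged from -0.26 to 0.38 (without Adult control 3) for macrophage and from -0.66 (without Adult burn 3) to 0.47 for lipid-associated macrophage genes. Without Adult control 1 and Adult burn 1 together they were 0.34 (cell cycle), 0.22 (immediate early) and -0.30 (erythroid). For the difference between ages they ranged from 0.16 (without Adult control 1, the test pointing down) to 4.36 for T and NK cell genes and from -4.82 to 0.36 (without Adult burn 1) for skeletal muscle. For age they ranged from -0.67 to -0.05 (without Adult control 3, the test pointing up) for oxidative phosphorylation. No called named gene changed sign in any alternative. At this depth genes under about 1 CPM rest on few reads.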

Other observations

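The test of Socs2 and Igf1 was set before their values were seen. In burned aged mice some single genes not described above also rose, picked from several lists of which some had members in both directions: Gdf15, a stress-induced hormone, from 0.887 ± 0.493 to 17.5 ± 3.2 CPM (edgeR adjusted p = 0.00569), the transcription factor gene Atf3 from 3.86 to 60.3 CPM, heme oxygenase Hmox1 from 30 ± 4.77 to 627 ± 552 CPM, the creatine transporter Slc6a8 from 29.1 to 110 CPM and the secreted factor Metrnl from 16 to 113 CPM. The lipid droplet coat gene Plin2 rose from 301 to 1270 CPM, while Mogat1, of triglyceride synthesis, fell from 31.9 to 8.65 CPM. The lactate transporter Slc16a3 rose from 0.693 to 70.7 ± 84 CPM, and the hexokinase genes parted, with Hk1 rising by log2 0.78 and Hk2 changing by log2 -1.17 (adjusted p = 0.0309 and 0.0313).

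The fall of Cish in burned aged mice raised the hypothesis of lower growth hormone signalling through STAT5, of which Cish, Socs2 and Igf1 are targets. Cish was at 24.5 to 82.6 CPM in aged controls and 3.71 to 5.48 CPM in burned aged mice. The latter lay within the range of adult controls (1.35 to 11.4 CPM), so the fall started from high and variable aged controls. The predicted fall of Socs2 and Igf1 was not borne out: the log2 fold change of Socs2 was 0.14 ± 0.23 SE and that of Igf1 -0.25 ± 0.18 SE (edgeR adjusted p = 0.678 and 0.323). Both were measured in whole tissue, where macrophage genes rose (median log2 2.85) and adipocyte identity genes were lower (-1.04). Lower signalling in adipocytes alone is therefore not excluded.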
